A study of Mus musculus with 12 samples.

How the data were processed

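The data are expression arrays of mouse liver, 12 samples in 3 groups of 4 (wild type, transgenic for constitutively active FoxO3, and transgenic given metformin). Groups and replicate numbers were taken from the sample titles, which call the samples biological replicates. Per the labels, RNA was extracted from livers kept in RNAlater with a column kit, labelled with biotin by an assay for sense-strand targets of whole transcripts and hybridised to Affymetrix arrays, 1 sample per array. The submitters' processing notes name Affymetrix Expression Console without a version. The deposited value table holds log2 signals, as its range shows, with 1 column per sample and 35556 rows. The summarisation, background correction and normalization the authors used to make these log2 values are not given in the sources used here, and neither are scan dates. The p-values rest on the labels' statement that the 4 samples of a group are biological replicates. Array medians lay between 5.69 and 5.85 and maxima between 14.16 and 14.31, so the arrays were already on a common scale, and no further normalization was applied. How far a dim probe set lies above background cannot be read from these values.

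Rows were named through the platform's annotation table. It names 23410 of the rows, 21789 of them with 1 gene and 1621 with several; the other 12146 rows are unnamed here. Only rows with 1 gene were used. Symbols were looked up by Entrez identifier in a RefSeq gene table, which matched 21698 rows and changed 0 symbols. Where a gene had several rows (999 genes), the row with the highest mean over all arrays stood for it, which left 19938 genes, and the 25% with the lowest mean were left out, which left 14953. The dimmest tested gene had a mean of 4.86.

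Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, contrasts of the group means with all 12 arrays in 1 fit and no covariate), with Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05. A difference among the 3 groups was tested with limma's moderated F test. Every adjusted p of a single gene comes from limma, and values after ± are standard errors of the fit unless called SD. The fit gives each gene 1 residual spread for all 3 groups. Where the groups differ in spread, these standard errors and p-values can be too small or too large for a single comparison. Gene lists (41, all with at least 5 measured members) were written from general knowledge of liver biology and were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a contrast. No list was called in any contrast when camera estimated the correlation from the data. The fry test, which asks whether a list's genes move on balance one way and does not compare the list with other genes, called 4, 16 and 0 lists for transgenic against wild type, metformin-treated against transgenic, and metformin-treated against wild type. Foxo3 was compared with a two-sided exact permutation test.

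The genes named in the text follow a rule. The design, this rule, the gene lists and the alternatives below, except those said to be added, were fixed before the data were examined. The rule names Foxo3; per comparison the 10 highest and 10 lowest log2 changes among called genes whose 4 arrays in one group all lay above the 4 of the other, leaving out predicted genes, small RNAs and near-identical families; and per described list up to 4 called members with the smallest p, or, if none was called, the first members in list order. Kdm5d entered as part of the Y-linked signal. Genes named in the closing section that fall outside this rule were chosen after their values were seen. Groups that do not overlap at all are expected by chance for 2.86% of genes; they made up 21.9%, 21.6% and 14.4% of the tested genes in transgenic against wild type, metformin-treated against transgenic, and metformin-treated against wild type.

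The sex covariate is Xist minus the mean of the Y-linked genes of each array, centred. It was fitted as an added term. Since all transgenic arrays have Y-linked signal and all metformin-treated arrays Xist signal, this term is estimated almost wholly from the 4 wild type arrays and assumes that sex acts alike in all groups. Arrays are called arrays with Y-linked signal or with Xist signal by these transcripts; no sex is given in the labels. Alternatives also included the dim-gene filter (none, and 50%), the mean of all rows of a gene, quantile normalization, median centring, eBayes with trend and robust settings, array weights, the replicate number as a block, only the 8 arrays compared, other thresholds and each array left out. Fits on arrays of 1 kind of sex signal only, and with the sex covariate and an array left out together, were added after the data were seen. The test of hepatocyte share in the closing section is the last of 3 forms, all written after the data were seen: the first restated the pattern it was to explain, and another took genes as independent (p from the chi-square distribution).

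The functions were tested on simulated arrays with the means and residual spread of the real 14953 genes and 200 changed genes. For transgenic against wild type, 44.8% of changes of 0.5, 83.6% of changes of 1 and 100% of changes of 2 (log2) were called; for metformin-treated against transgenic the shares were 59.7%, 82.1% and 98.5%, and for metformin-treated against wild type 59.7%, 86.6% and 100%. False calls made up 3.73%, 4.62% and 4.44%. Simulated genes were independent, so this says nothing about lists of correlated genes. Figures were drawn with matplotlib 3.10.9.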

Results

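Liver RNA of 12 mice was measured on one-colour whole-transcript arrays, one array per animal. All animals were 7 weeks old and came from C57BL/6 and NMRI stock crossed back to C57BL/6 at least 4 times. They formed 3 groups of 4. These were wild type controls, mice carrying a constitutively active form of FoxO3 under the LAP promoter, and mice with the same transgene given metformin, a glucose-lowering biguanide. FoxO3 is a forkhead transcription factor that insulin signalling normally keeps out of the nucleus. The labels give no dose, route or duration of metformin and no sex. The value table held 35556 rows on a log2 scale, with array medians between 5.69 and 5.85, and 14953 named genes were tested. The number of arrays limits the precision. No wild type animals given metformin are among the 12, so whether metformin acts differently with and without the transgene was not tested.

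The animals differed in transcripts of the sex chromosomes. Xist, the RNA that coats the inactive X chromosome, read between 4.24 and 4.70 in the 4 transgenic livers and between 10.57 and 11.95 in the 4 metformin-treated transgenic livers. Among wild type livers it read 11.73 and 11.66 in replicates 1 and 4, and 4.36 and 4.30 in replicates 2 and 3. The Y-linked gene Eif2s3y ran the other way, between 8.43 and 8.93 in the arrays with low Xist and between 3.77 and 4.30 in those with high Xist. The comparison of metformin-treated with untreated transgenic livers therefore also sets high-Xist against low-Xist animals. Values from a fit with the difference between Xist and Y-linked signal as a covariate (the sex covariate below) are given for the named genes with the largest changes, for the counts, and for lists whose call they end. In that fit only the wild type animals separate this signal from the groups. Across genes, transgenic replicate 2 correlated more closely with the wild type arrays (mean r = 0.984) than with its own group (0.968). Metformin-treated replicate 3 had the lowest mean correlation with its own group among the metformin-treated arrays (0.974).

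**Figure D1:**
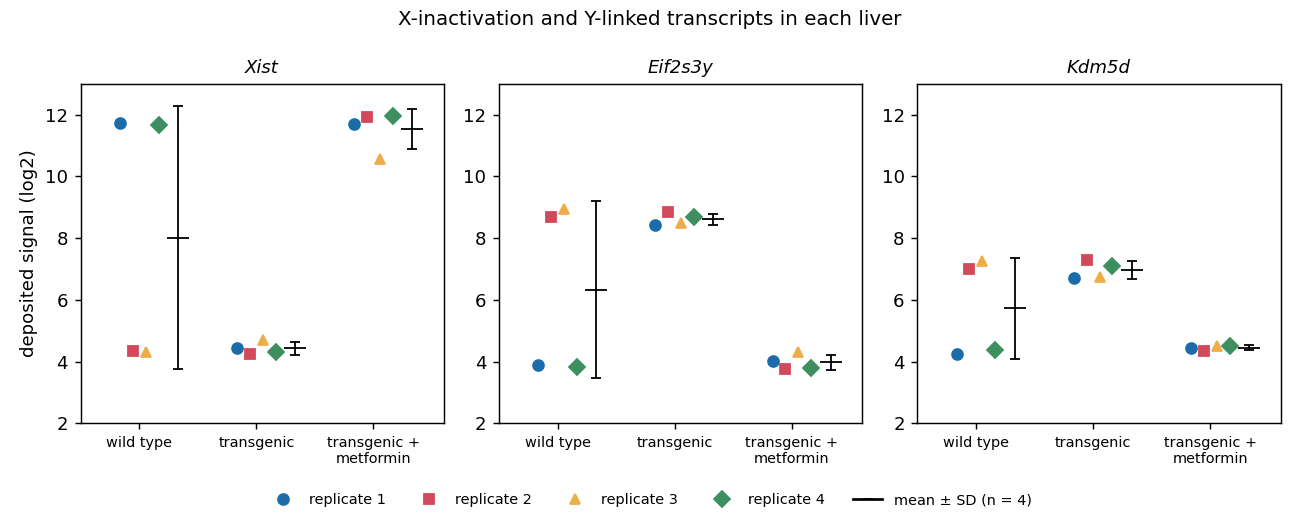
Deposited log2 signal of Xist and of the Y-linked genes Eif2s3y and Kdm5d in each of the 12 livers, by group; symbols mark the replicate, and bars the mean and SD of 4 arrays. The transgenic livers all have Y-linked signal, the metformin-treated livers all have Xist signal, and the wild type group holds both kinds.

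Foxo3 itself, read by 1 probe set, did not differ detectably between groups. It stood at 8.82 ± 0.16 (SD, n = 4) in transgenic and 8.77 ± 0.16 in wild type livers, a difference of 0.05 (two-sided exact permutation test, p = 0.571; the smallest p the design allows is 0.0286), whose sign turned under quantile normalization and median centring. The 95% interval of the limma fit ran from -0.29 to 0.40. In metformin-treated livers the level was 8.80 ± 0.36. Whether these probes detect the transgene's RNA is not given in the sources used here, so the value checks nothing about the labels.

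Transgenic livers were compared with wild type livers; all 4 transgenic arrays have Y-linked signal and 2 of the 4 wild type arrays have Xist signal. Known FoxO-responsive genes were higher in transgenic livers. Igfbp1, an insulin-repressed binding protein for insulin-like growth factors, was higher by 3.41 ± 0.64 on the log2 scale (limma estimate ± SE, n = 4 per group, adjusted p = 0.00789), and Pdk4, the kinase that restrains pyruvate oxidation, by 3.86 ± 0.72 (adjusted p = 0.00777). The largest increases chosen by the naming rule were those of the secreted glutathione peroxidase Gpx3 (5.49 ± 1.01, adjusted p = 0.00723) and the leptin receptor Lepr (4.82 ± 0.78, adjusted p = 0.00423). Among the genes with the largest decreases, the lipogenic gene Thrsp fell by 2.47 ± 0.40, the carboxylesterase gene Ces1f by 3.28 ± 0.74 and the deiodinase Dio1 by 3.02 ± 0.68.

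Other genes with the largest increases were Atp6v0d2, a subunit of the vacuolar proton pump (3.56 ± 0.65), the fetal serum protein Afp (3.03 ± 0.73) and Epdr1 (3.02 ± 0.33). They were followed by the anion exchanger Slc4a9 (2.86 ± 0.69), the glycogen-targeting subunit Ppp1r3g (2.80 ± 0.65) and the lipopolysaccharide co-receptor Cd14 (2.72 ± 0.52). The lowest values among the named genes also included Mug2 (-2.66 ± 0.66), the sodium channel subunit Scnn1a (-2.55 ± 0.41) and the carbonic anhydrase Car1 (-2.47 ± 0.55). Next came the carboxylesterases Ces1e (-2.24 ± 0.47) and Ces1b (-2.20 ± 0.44), the transporter Slc22a30 (-2.23 ± 0.55) and the aquaporin Aqp8 (-2.17 ± 0.44). Of the 20 largest changes named here, only Atp6v0d2 had a larger SD in wild type (1.59) than in transgenic livers (0.87). The others varied more in transgenic livers, such as Igfbp1 (SD 1.69 against 0.44) and Afp (2.07 against 0.095). Since the fit pools the spread of all 3 groups, their standard errors and p-values may be too small. In the fit with the sex covariate Gpx3, Lepr, Pdk4, Atp6v0d2, Igfbp1, Epdr1, Cd14, Scnn1a, Thrsp and Ces1e stayed under an adjusted p of 0.05. The other 10 of these 20 genes did not, although their estimates stayed at 89.7% to 107% of those without it, so these calls were lost to precision and not to size. All 20 passed when transgenic replicate 2 was left out of that fit as well, a fit chosen after the data were seen. With only arrays with Y-linked signal, a fit with fewer arrays also chosen after the data were seen, 19 of the 20 did not pass. Transgenic replicate 2 lay between wild type and the other transgenic livers for several of these genes. Igfbp1 read 10.09 there and 13.35 to 13.54 in the other 3 livers, Gpx3 10.09 against 13.27 to 13.48, and Afp 5.64 against 8.31 to 10.31. Epdr1 read 8.52 there and lay within the range of the others.

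**Figure D2:**
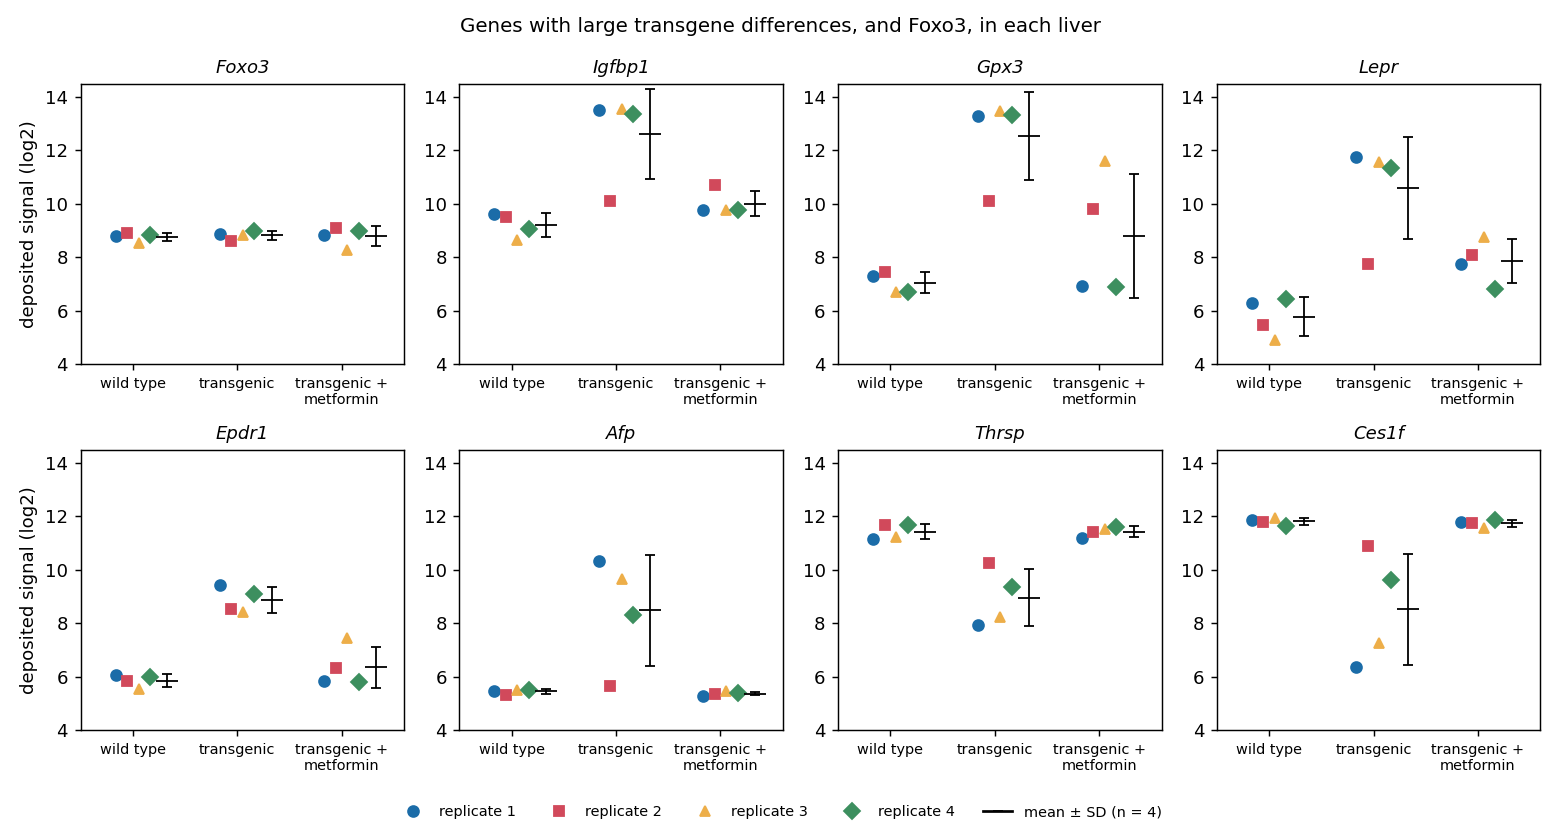
Deposited log2 signal of Foxo3 and 7 genes that differed between transgenic and wild type livers, per liver and group; symbols mark the replicate, and bars the mean and SD of 4 arrays. Transgenic replicate 2 lies nearer the wild type level for Igfbp1 and Afp and within its group for Epdr1; metformin-treated replicates 2 and 3 lie above the wild type livers for Gpx3.

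Of 42 measured FoxO targets, 19 rose and 1 fell (22 and 2 when adjusted over the list alone), with a median log2 change of 0.43 (camera, adjusted p = 3.04e-08; adjusted p = 0.122 with an estimated correlation). The members with the smallest p were Sesn3 (1.33 ± 0.15) and Sesn1 (0.98 ± 0.12), stress-induced sestrins, the DNA damage-binding protein Ddb1 (0.85 ± 0.10) and Txnip (2.05 ± 0.27), an inhibitor of thioredoxin. In the insulin, growth hormone and IGF list 10 of 27 members rose and 4 fell (10 and 5 when adjusted over the list alone; camera, adjusted p = 0.0257; adjusted p = 0.722 with an estimated correlation). Among them were Igfbp2 (2.09 ± 0.33), Foxa1 (0.89 ± 0.11) and Akt1 (0.67 ± 0.099). In the autophagy and lysosome list 7 of 32 members rose and 2 fell (10 and 2 when adjusted over the list alone; adjusted p = 0.0173, and 0.722 with an estimated correlation). Its smallest p values were those of Wipi1 (1.17 ± 0.14) and the autophagosome protein gene Map1lc3b (0.54 ± 0.13). Without transgenic replicate 2 the FoxO list had 22 members up and 2 down, and neither the insulin list (adjusted p = 0.107) nor the autophagy list (adjusted p = 0.193) was called.

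Lipid-synthesis and hepatocyte-function lists were lower. Of 25 genes of fatty acid synthesis 13 fell and 0 rose (18 and 0 when adjusted over the list alone; median -0.45, camera adjusted p = 1.43e-06, and adjusted p = 0.722 with an estimated correlation). They included the regulator Srebf1 (-1.21 ± 0.21), Mid1ip1 (-0.82 ± 0.17) and the triglyceride-forming enzyme Dgat2 (-0.57 ± 0.13). In the urea cycle and amino acid list 10 of 35 fell and 0 rose (13 and 1 when adjusted over the list alone; adjusted p = 5.08e-04, and 0.722 with an estimated correlation). There Gpt stood at -1.0 ± 0.16 and the urea cycle enzyme Arg1 at -0.94 ± 0.19. In the bile acid list 8 of 29 fell and 3 rose (12 and 3 when adjusted over the list alone; adjusted p = 0.0033, and 0.722 with an estimated correlation). Its members included the bile acid importer Slc10a1 at -0.68 ± 0.17 and the receptor Nr1h4 at -0.63 ± 0.16. Among secreted liver proteins 7 of 34 fell and 0 rose (11 and 0 when adjusted over the list alone; adjusted p = 3.40e-04, and 0.722 with an estimated correlation). Among these were the clotting factors F7 (-1.17 ± 0.24) and F11 (-1.87 ± 0.40). The periportal hepatocyte list had 6 of 21 members down and 1 up (6 and 1 when adjusted over the list alone; adjusted p = 0.0189, and 0.722 with an estimated correlation), with Cyp2f2 at -1.56 ± 0.39. The complex I list had 3 of 35 down and 0 up (1 and 0 when adjusted over the list alone; adjusted p = 0.0189). The cholesterol synthesis list had 2 of 21 down and 0 up (0 and 0 when adjusted over the list alone; adjusted p = 0.0255). For both the adjusted p was 0.738 with an estimated correlation, and the cholesterol list was not called without transgenic replicate 2 (adjusted p = 0.0904). Without that replicate the numbers of members down were 17 for the urea cycle list, 15 for bile acids, 17 for secreted proteins and 7 for complex I. The sex covariate ended the calls of the periportal (adjusted p = 0.0784) and cholesterol (0.116) lists, with 0 members of either called and medians of -0.15 (-0.23 without it) and -0.24 (-0.32). It left the medians of the fatty acid (-0.45), bile acid (-0.46) and secreted protein (-0.20) lists in place, but only 2, 0 and 1 members down.

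Of 23 Kupffer cell and macrophage markers 5 rose and 0 fell (9 and 0 when adjusted over the list alone; median 0.66, camera adjusted p = 2.71e-05, and adjusted p = 0.722 with an estimated correlation). Among the 5 were Cd5l (1.03 ± 0.22), the complement gene C1qa (0.71 ± 0.15) and Clec4f (0.62 ± 0.16); without transgenic replicate 2, 13 of the 23 rose. In the cell cycle list 3 of 39 rose and 0 fell (1 and 0 when adjusted over the list alone; median 0.52, adjusted p = 7.68e-05, and 0.738 with an estimated correlation). These were the replication genes Mcm6 (1.37 ± 0.31), Mcm5 (0.73 ± 0.21) and Pcna (0.57 ± 0.16). Over all genes 1192 of 14953 rose, a share close to that of this list. Without transgenic replicate 2, 21 of the 39 rose, in a fit that called 4004 genes in place of 2111. In the fetal liver and tumour list 4 of 17 rose and 0 fell (5 and 0 when adjusted over the list alone; adjusted p = 0.0189, and 0.722 with an estimated correlation): Afp, Tff3 (1.5 ± 0.40), Ly6d (2.36 ± 0.66) and Gpc3 (1.86 ± 0.53). Without transgenic replicate 2, 8 of the 17 rose. Of 24 male-biased liver genes 2 fell and 0 rose (2 and 0 when adjusted over the list alone; median -0.58, adjusted p = 0.0284, and 0.738 with an estimated correlation). They were the reductase Hsd11b1 (-1.34 ± 0.31) and Gna14 (-0.95 ± 0.22), and without transgenic replicate 2, 11 fell. In the sex covariate fit 0 members of the cell cycle and fetal lists and 1 of the autophagy list passed, with all 3 lists still called. That fit gave the male-biased list a median of -1.25 and the female-biased list one of 0.25, against -0.14 without it. The Xist signal of these groups differs as given above. 

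In all, limma called 2111 of 14953 genes between transgenic and wild type livers, 1192 higher and 919 lower, and camera called 14 of 41 lists, 6 up and 8 down (0 with an estimated correlation). With each array centred on its median the share of higher genes went from 56.5% to 43.9%. With the sex covariate 650 genes were called, 600 of them also without it and in the same direction, and 3013 when transgenic replicate 2 was left out as well. Leaving out single arrays gave 1138, 4004, 764 and 1198 genes without transgenic replicates 1 to 4. The counts were 941, 1103, 1187 and 1034 without wild type replicates 1 to 4, and 3254 without metformin-treated replicate 3.

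Metformin-treated transgenic livers were compared with untreated transgenic livers, which also differ from them in Xist signal. Genes with sex-biased expression in mouse liver made up much of the largest differences. The sulfotransferase Sult3a1 was higher by 7.11 ± 1.51 (adjusted p = 0.00612), Xist by 7.10 ± 1.52 and the cytochrome Cyp2b13 by 5.75 ± 1.09. The Y-linked genes Eif2s3y and Uty fell by 4.63 ± 1.02 and 3.43 ± 0.88. Genes raised in untreated transgenic livers were lower with metformin, among them Afp (-3.11 ± 0.73, adjusted p = 0.0101), Epdr1 (-2.53 ± 0.33, adjusted p = 5.85e-04) and Cd14 (-2.51 ± 0.52, adjusted p = 0.00543). The carboxylesterase Ces1f, low in the transgenic group, rose by 3.21 ± 0.74. In wild type livers the sex-biased gene Sult3a1 split in the same way and read 10.30 and 11.01 in wild type replicates 1 and 4 and 3.24 and 3.39 in replicates 2 and 3. The fit also holds these wild type arrays, so their split widened the standard errors of Sult3a1 and Xist. In metformin-treated and untreated transgenic livers the SDs were only 0.34 and 0.22 for Sult3a1 and 0.65 and 0.20 for Xist.

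Further genes among the largest differences were Cyp3a16 (4.92 ± 0.96), Sult3a2 (4.88 ± 1.06), the oxidase Hao2 (4.48 ± 0.95), Slc22a26 (4.18 ± 1.20), Cyp2a22 (3.97 ± 0.82) and the lysolipid transporter Mfsd2a (3.22 ± 0.67), all higher with metformin. Lower with metformin were Cyp4a12b (-4.52 ± 1.49), the proto-oncogene Myc (-2.70 ± 0.43), the interleukin 22 receptor subunit Il22ra1 (-2.65 ± 0.33), the activin antagonist Fst (-2.65 ± 0.49) and Cib3 (-2.58 ± 0.50). None of the 20 genes chosen by the naming rule passed an adjusted p of 0.05 in limma with the sex covariate, but 7 did (Ces1f, Afp, Myc, Il22ra1, Fst, Epdr1 and Cd14) when transgenic replicate 2 was left out as well. In the fit with all arrays the estimates of Slc22a26 (-1.02), Cyp4a12b (1.15) and Uty (0.54) changed sign. Those of Afp (-3.34), Epdr1 (-2.72), Cd14 (-2.70), Myc (-2.72) and Ces1f (3.45) were at least as large as without it. Of the 20 genes 7 kept at least 90% of their estimate and 13 did not, those that changed sign included. Among the 13 were Xist (0.21), Sult3a1 (0.45), Cyp2a22 (0.46), Hao2 (0.72) and Cyp2b13 (0.95), of which little was left.

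Of 42 FoxO targets 22 fell and 2 rose with metformin (24 and 3 when adjusted over the list alone; median -0.50, camera adjusted p = 1.47e-05, and adjusted p = 0.415 with an estimated correlation). Sesn3 fell by 1.40 ± 0.15, the coactivator-binding protein Cited2 by 1.47 ± 0.17, Ddb1 by 0.83 ± 0.10 and the translation repressor Eif4ebp1 by 0.78 ± 0.11. The insulin, growth hormone and IGF list had 12 of 27 members down and 3 up (13 and 4 when adjusted over the list alone; adjusted p = 0.0232, and 0.508 with an estimated correlation). Among them were Foxa1 (-1.42 ± 0.11), the insulin receptor substrate Irs2 (-2.19 ± 0.33) and Igfbp2 (-2.09 ± 0.33). Sesn3 and Foxa1 kept adjusted p values of 0.0239 and 0.0239 in limma with the sex covariate, a fit that called 82 genes in all against 3695 without it. In the heat shock and immediate early list 9 of 26 fell and 2 rose (11 and 2 when adjusted over the list alone; adjusted p = 0.0102, and 0.648 with an estimated correlation), with Hspb1 at -2.18 ± 0.32; its call ended with the sex covariate (adjusted p = 0.0603, 0 members called), with a median of -0.32 against -0.38 without it. Of the Kupffer cell and macrophage markers 5 of 23 fell and 1 rose (6 and 1 when adjusted over the list alone; adjusted p = 0.00762, and 0.653 with an estimated correlation), with Cd68 at -1.03 ± 0.28. Without metformin-treated replicate 3, where Cd68 read 7.58 against 8.56 to 8.81 in the other 3 livers, the macrophage list (adjusted p = 0.146), the heat shock list (0.0603) and the insulin list (0.0603) were not called; the insulin list was not called without transgenic replicate 2 either (0.0607). The number of macrophage markers down was 1 without metformin-treated replicate 3 and 11 without transgenic replicate 2.

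Most lists that were low in the transgenic group were higher with metformin. Both comparisons hold the same transgenic arrays with opposite signs, which by itself favours such a reversal. No list was tested with these arrays split between the comparisons. The same limit applies to the FoxO, insulin and macrophage lists above. Of the 25 fatty acid synthesis genes 12 rose and 1 fell (16 and 2 when adjusted over the list alone; median 0.49, camera adjusted p = 5.76e-05, and adjusted p = 0.508 with an estimated correlation). The smallest p was that of Thrsp (2.48 ± 0.40), followed by genes including Dgat2 (0.65 ± 0.13) and the malic enzyme Me1 (0.59 ± 0.12). Of the 35 urea cycle and amino acid genes 15 rose and 0 fell (15 and 0 when adjusted over the list alone; adjusted p = 5.76e-05, and 0.508 with an estimated correlation), with Gpt at 1.01 ± 0.16. Of the 29 bile acid genes 13 rose and 0 fell (14 and 1 when adjusted over the list alone; adjusted p = 5.08e-04, and 0.508 with an estimated correlation). There Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 1.21 ± 0.20 and the sterol exporter subunit Abcg5 at 1.47 ± 0.25. The periportal list had 9 of 21 up and 1 down (11 and 2 when adjusted over the list alone; adjusted p = 0.00556, and 0.508 with an estimated correlation). The secreted protein list had 8 of 34 up and 0 down (8 and 0 when adjusted over the list alone; adjusted p = 0.00556, and 0.653 with an estimated correlation). Without transgenic replicate 2, 16 of the 34 secreted protein genes rose. The gluconeogenesis list had 6 of 20 up and 1 down (7 and 1 when adjusted over the list alone; adjusted p = 0.0238, and 0.508 with an estimated correlation). Neither the periportal list (adjusted p = 0.104, median 0.25 against 0.48 without it) nor the gluconeogenesis list (0.0873, median 0.24 in both fits) was called with the sex covariate, and 0 members of any list in this paragraph passed in that fit.

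Of 27 female-biased liver genes 16 rose and 1 fell (16 and 1 when adjusted over the list alone; median 1.43, camera adjusted p = 1.28e-05, and adjusted p = 0.508 with an estimated correlation). Among them stood the very low density lipoprotein receptor Vldlr at 1.72 ± 0.28, Hamp2 at 2.13 ± 0.40 and Cux2 at 1.43 ± 0.27. Adding the sex covariate ended this call (adjusted p = 0.886), with a median of 0.41, 0 members up and 1 down. The male-biased list, not called without it (median -0.26), was called up in that fit (median 1.10, adjusted p = 0.00165, and 0.718 with an estimated correlation), with 0 members called. The xenobiotic list had 7 of 25 members up and 1 down (7 and 1 when adjusted over the list alone; adjusted p = 0.00501, and 0.508 with an estimated correlation). Among these were the receptor gene Nr1i3 (2.32 ± 0.42) and the female-biased Cyp2b13. This call also ended with the sex covariate (adjusted p = 0.416), which moved the median from 0.61 to 0.25 and left 0 members called. Of 8 sex chromosome genes 3 rose and 3 fell.

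Altogether limma called 3695 of 14953 genes between metformin-treated and untreated transgenic livers, 1583 higher and 2112 lower, and camera called 12 of 41 lists, 8 up and 4 down (0 with an estimated correlation). Centring each array on its median shifted this contrast by 0.11 and moved the share of higher genes from 42.8% to 65.6%. With the sex covariate limma called 82 genes (27 higher, 55 lower). Without transgenic replicate 3 the count was 2419, and with only these 8 arrays in the fit it was 2354.

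**Figure D3:**
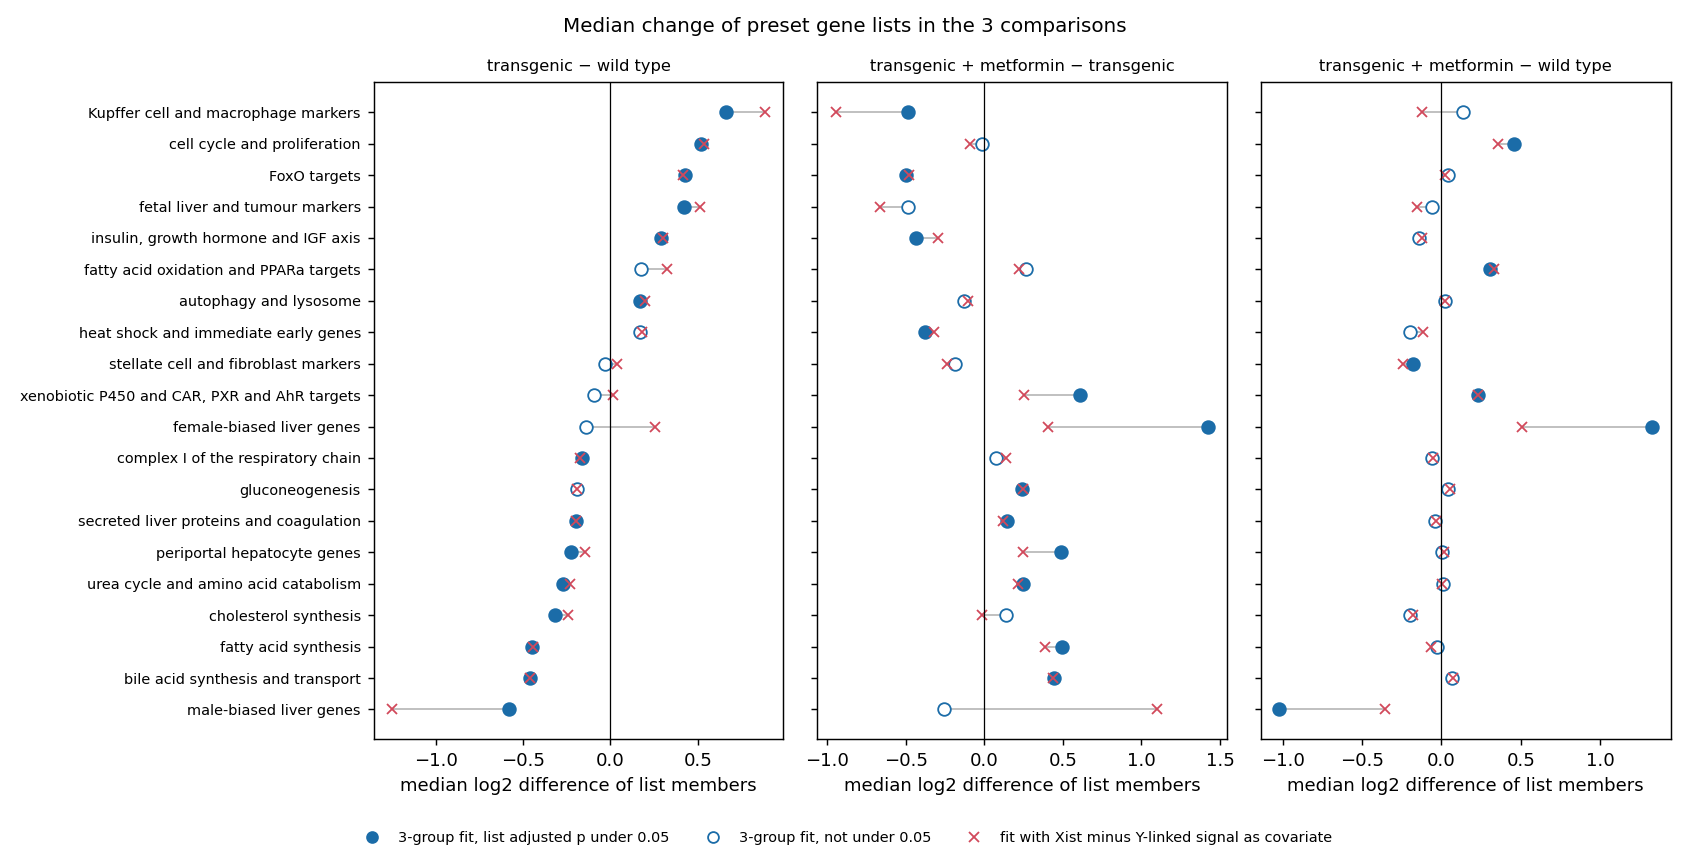
Median log2 difference of the measured members of each gene list called in at least 1 comparison, in the 3 comparisons; filled circles are lists called by camera at an adjusted p under 0.05, open circles lists not called, and crosses the median in the fit with the sex covariate. FoxO targets have medians of 0.43, -0.50 and 0.04 in the 3 comparisons, and the sex-biased lists move most between the fits.

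Changes with metformin ran opposite to those with the transgene across genes. Of the 1192 genes higher in transgenic than in wild type livers 878 fell with metformin and 0 rose. Of the 919 lower genes 636 rose and 1 fell. Independent lists would share 168 and 97.3. That is no fair reference here, since both comparisons hold the transgenic arrays with opposite signs, and no other was computed for the counts. For this reason the covariance of the log2 changes was also computed with these arrays split 2 and 2. It was -0.127 (SD 0.0103 over 6 splits, from -0.141 to -0.115; correlation across genes -0.668). With all arrays it was -0.147, against -0.0151 in simulated data without any effect, a difference of -0.132. Genes are not independent replicates, so no p is given. The transgenic and metformin-treated arrays differ in Xist signal here too.

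Metformin-treated transgenic livers were finally set against wild type livers, of which 2 have Y-linked signal. The thioesterases Acot3 and Acot4 were higher by 3.04 ± 0.67 and 1.87 ± 0.41 (adjusted p = 0.0394 for both), the fatty acid transporter Cd36 by 1.00 ± 0.15 (adjusted p = 0.0109) and Cyp2a22 by 3.56 ± 0.82. Socs2, a feedback inhibitor of growth hormone signalling, was higher by 1.42 ± 0.31 and the AMPK subunit gene Prkaa2 by 0.64 ± 0.11 (adjusted p = 0.0186). Prkaa2 belongs to the metformin transport and AMPK list, which camera did not call in this comparison. Without metformin-treated replicate 3, 1 of its 15 measured members rose and 0 fell (camera, adjusted p = 0.267, and adjusted p = 0.659 with an estimated correlation). The transcriptional regulators Bcl3 (-1.22 ± 0.16, adjusted p = 0.0078) and Nfic (-1.26 ± 0.19) and the adhesion protein gene Nectin1 (-1.0 ± 0.13) were lower. Of 42 FoxO targets 0 rose and 0 fell (0 and 0 when adjusted over the list alone; median 0.043, camera adjusted p = 0.611, and adjusted p = 0.956 with an estimated correlation).

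Others among the higher genes were Nipal1 (2.01 ± 0.47), the sialyltransferase St3gal6 (1.92 ± 0.31), Vldlr (1.47 ± 0.28), the pantetheinase Vnn1 (1.30 ± 0.28), Naaladl2 (1.05 ± 0.19) and Alg6 (1.03 ± 0.18). Lower were Lad1 (-1.27 ± 0.25), Zfhx2 (-1.04 ± 0.13), Denn2b (-1.02 ± 0.17), Mn1 (-1.0 ± 0.18), the corepressor Tle3 (-0.99 ± 0.23), the lysosomal sulfatase Arsa (-0.97 ± 0.23) and Cecr2 (-0.94 ± 0.20). With the sex covariate St3gal6 (1.29, adjusted p = 0.0331), Zfhx2 (-1.06, adjusted p = 0.0472) and Cd36 (0.70, adjusted p = 0.0297) stayed under the threshold. Of the 18 genes chosen by the naming rule that did not, 9 kept at least 90% of their estimate, such as Bcl3 (-1.24), Nfic (-1.28) and Socs2 (1.54). The other 9 shrank, most of all Cyp2a22 (1.78). St3gal6 read between 9.71 and 9.86 in metformin-treated livers, 8.16 and 8.92 in wild type replicates 1 and 4, and 7.07 and 7.28 in replicates 2 and 3.

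In the fatty acid oxidation and PPARa list 6 of 34 genes rose and 0 fell (10 and 0 when adjusted over the list alone; median 0.30, camera adjusted p = 4.05e-08, and adjusted p = 0.661 with an estimated correlation). Of 27 female-biased genes 5 rose and 0 fell (15 and 0 when adjusted over the list alone; median 1.33, adjusted p = 4.86e-13, and 0.661 with an estimated correlation). Of 24 male-biased genes 0 were called over all genes (0 up and 3 down when adjusted over the list alone; median -1.02, adjusted p = 5.14e-06, and 0.766 with an estimated correlation). The sex covariate moved the female-biased median to 0.51 and the male-biased one to -0.35, and the male-biased list was not called in that fit (adjusted p = 0.0917). The cell cycle list had a median of 0.46 (adjusted p = 4.05e-08, and 0.766 with an estimated correlation) with 0 members called (0 when adjusted over the list alone). Its genes Mki67 and Top2a had values of 0.88 ± 0.33 and 0.99 ± 0.32 that did not pass. The xenobiotic list (0 of 25 called, 3 up when adjusted over the list alone; adjusted p = 4.25e-04, and 0.661 with an estimated correlation) was called up. The stellate cell list (0 of 22 called, 0 when adjusted over the list alone; adjusted p = 0.0381, and 0.89 with an estimated correlation) was called down, but not without metformin-treated replicate 3 (adjusted p = 0.264).

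In this comparison limma called 364 of 14953 genes, 148 higher and 216 lower, and camera called 6 of 41 lists, 4 up and 2 down (0 with an estimated correlation). Median centring moved the share of higher genes from 40.7% to 64.0%. With the sex covariate 14 genes were called, 7 in each direction (1763 at an unadjusted p under 0.05). Leaving out single arrays gave 616 genes without transgenic replicate 2, 87, 96, 91 and 137 without wild type replicates 1 to 4. It gave 150, 145, 775 and 70 without metformin-treated replicates 1 to 4. A test for any difference among the 3 groups called 3613 genes, 340 with the sex covariate and 1998 without transgenic replicate 3.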

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

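The tests of the 3 patterns weighed here were chosen after the results were seen; the counts over other splits of the arrays were planned. Every split of the 8 arrays of a comparison into 4 and 4 was fitted (35 splits, the real one included). For transgenic against wild type 1 of the 35 splits, the real one, gave as many genes (2111; the highest other gave 5). The same held for metformin-treated against untreated transgenic (1 of 35; 3695 against 1113, in the split that exchanges transgenic replicate 2 and metformin-treated replicate 3) and for metformin-treated against wild type (1 of 35; 364 against 1). For a difference among the 3 groups 1 of 100 splits gave as many (3613; highest other 287). The real split thus ranked first for each count, the best rank that 35 or 100 splits allow, and the 3 comparisons share arrays. This argues against chance for these counts without excluding it. For the numbers of gene lists there is no such argument. There 16, 17 and 27 of the 35 splits gave at least as many lists as the real 14, 12 and 6, with up to 20, 20 and 16 lists in another split.

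All metformin-treated transgenic arrays have Xist signal and all untreated transgenic arrays Y-linked signal, so sex is the first explanation to weigh for their differences. For the 29 called sex-biased genes, the difference between wild type arrays with Xist and with Y-linked signal had a median of 0.822 of the change (bootstrap over genes 0.671 to 0.896), which is consistent with a sex difference as the source of most of that change. For the 1514 genes that changed one way with the transgene and the other way with metformin the median was 0.0326 (0.0202 to 0.0459). A low value is partly built in, since these genes had to be called against wild type, where a sex difference widens the spread. Over all 3695 genes called between the metformin-treated and untreated groups, without that requirement, it was 0.0293 (0.0202 to 0.0367). The wild type arrays enter the spread of that fit as well, so a low value is partly built in there too. These intervals resample genes and leave out the uncertainty from the few wild type arrays. The ratio therefore does not decide whether the sex difference seen in wild type livers is the source for the 1514 genes. Whether the 1514 genes differ because of metformin or because animals of the other sex respond less to the transgene cannot be told apart. The reason is that 0 metformin-treated arrays have Y-linked signal and 0 untreated transgenic arrays Xist signal. Both stay open, metformin included, as does the sex difference seen in wild type livers.

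Transgenic replicate 2 lies near the wild type arrays: over 3013 genes fitted without it, its median position was 25.1% of the way from wild type to the other transgenic arrays, with Epdr1 at 85.5%, Atp6v0d2 at 73.8%, Gpx3 at 47.9% and Afp at 5.46%; Sesn3 read 10.62 there, 10.05 to 10.44 in the other transgenic and 8.66 to 9.41 in the wild type arrays. For a wild type animal labelled transgenic, the share of genes beyond all other wild type arrays on the transgenic side was at least 54.0%, against at most 36.3% for a left-out wild type array, just under the 1.5 times set as the bound. The share of genes past the midpoint towards the other transgenic arrays was at least 16.5% against at most 7.96%, over that bound. This test was added once genes at the transgenic level had been seen, so passing its bound is weak evidence. Both shares lay above those of every left-out wild type array, which argues only weakly against this explanation. A weaker transgene cannot be judged from Foxo3, which read 8.60 there, because this probe set was not detectably higher in the transgenic group, so it stays open, and no other biological explanation was tested.

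In the comparison of arrays with Y-linked signal, chosen after seeing the data, 22 of 27 female-biased genes were higher in transgenic than in wild type livers (median 0.42), and 1 of 24 male-biased genes was (median -1.27), but of both lists only Cd36 was among the 9 genes called in that fit. RNA of female livers mixed into these samples would bring Xist. Linear signals were placed as a percent of the way from wild type arrays with Y-linked signal to those with Xist signal. The highest position of Xist in a transgenic array was 0.177%. The median position was 72.8% for the female-biased genes called with the sex covariate and at least 2-fold higher in wild type arrays with Xist signal. This argues against such a mixture. A lower share of hepatocyte RNA would raise the markers of all other cell types alike, but means ran from 0.076 for stellate to 0.77 for Kupffer cell markers (Cochran's Q, permutation of genes over 4 lists, p = 1.00e-04). Of the 15 splits of these arrays 5 gave a Q as large. The bound set for that share could not have been met, since the real split is itself 1 of the 15. The splits therefore cannot decide, and a lower hepatocyte share stays open. With the covariate 6 of the 27 passed and camera gave an adjusted p of 0.00231, but 0.62 with an estimated correlation, so an effect of the transgene on sex-biased expression is no more than a hypothesis.

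Single arrays far from the other 3 of their group were sought for the 102 genes named in the report, in 306 gene and group pairs, and 29 stood out, where chance gives about 1 in 20. The values are the gap to the nearest other array over the range of the group. In metformin-treated replicate 3 they were Bcl3 (0.839), Cux2 (0.892), Cyp2a22 (0.868), Eif4ebp1 (0.92), F7 (0.866), Foxa1 (0.854), Irs2 (0.937), Map1lc3b (0.831), Nectin1 (0.841), Nfic (0.93), Nr1i3 (0.861) and Tle3 (0.845). Other genes, picked after their values were seen, differed there from the mean of the other 3 arrays, such as Malat1 (-1.77), Kmt2d (-1.68), Snora44 (3.29) and Tomm5 (1.44). Without this array camera also called the proteasome list down in metformin-treated against transgenic (15 of 27 down, adjusted p = 1.28e-04). In metformin-treated against wild type it called down the proteasome (0.00177) and complex I (0.0011) lists and up the Kupffer cell (2.58e-04), circadian clock (0.0257) and B cell (0.0279) lists. With an estimated correlation these adjusted p values were 0.542 in the first of these comparisons and 0.659 for each list in the other. The genes that stood out in transgenic replicate 2 were Gpx3 (0.94), Igfbp1 (0.945), Lepr (0.898), Nipal1 (0.851) and Pdk4 (0.865), all low. The others were Denn2b in transgenic replicate 1 (0.889), Abcg5 in transgenic replicate 4 (0.924), Hamp2 in metformin-treated replicate 1 (0.897), and Aqp8 and Igfbp1 in metformin-treated replicate 2 (0.869 and 0.967). Among wild type arrays they were Ppp1r3g in replicate 2 (0.903), Cited2, F11 and Slc10a1 in replicate 3 (0.851, 0.836 and 0.845), and Cux2, Cyp3a16 and Dio1 in replicate 4 (0.941, 0.841 and 0.891).

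Probe sets without a gene name, which the report does not use, also differed between groups. Of 6209 bright enough to test, limma called 120 in transgenic against wild type, 958 in metformin-treated against transgenic and 110 in metformin-treated against wild type.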

How the results depend on the processing

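The fits on arrays of one kind of sex signal, those joining the sex covariate with a left-out array, and the covariance of differences matched for sex signal were chosen after seeing the data; the other alternatives were planned. Values below follow the order of comparison 1, transgenic against wild type (2111 genes in the main analysis), comparison 2, metformin-treated against transgenic (3695), comparison 3, metformin-treated against wild type (364), and any difference among the groups (3613). The cause of a change was not tested unless given.

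The sex covariate gave 650, 82, 14 and 340 genes, and turned Slc22a26 (-1.02), Cyp4a12b (1.15) and Uty (0.54) in comparison 2. Together with leaving out transgenic replicate 2 it gave 3013 genes in comparison 1, 1845 in comparison 2 and -1.33, 1.84 and 0.55 for these genes, and with metformin-treated replicate 3 left out 40 genes in comparison 3. Fewer arrays were compared with only arrays with Y-linked signal (9 genes, comparison 1) and with only arrays with Xist signal (1 gene, Nipal1, comparison 3). Array weights gave 4818, 6428, 3057 and 7577 genes. An adjusted p under 0.10 gave 3487 in comparison 1 and 837 in comparison 3, and a fold of at least 1.5 gave 1041, 1694 and 139, by construction. Trend and robust settings gave 227 in comparison 3, and only the 8 arrays compared gave 2354 in comparison 2. Camera with an estimated correlation called 0, 0 and 0 lists, and fry 4 in comparison 1 and 0 in comparison 3.

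Leaving out single arrays gave 764 to 4004, 2419 to 4828, 70 to 775 and 1998 to 5119 genes, and in comparison 3 5 to 10 lists. The covariance of transgene and metformin changes was negative in every setting run for it (array weights and the replicate block were not): -0.0966 with no filter on dim genes, -0.167 with 50% left out, -0.147 with all arrays in both contrasts, -0.432 over genes past the F test, and from -0.200 to -0.0852 without single arrays. It was -0.130 with no array on both sides, when the transgene change was taken within arrays with Y-linked signal and the metformin change as metformin-treated minus wild type (Xist signal) less transgenic minus wild type (Y-linked signal). This too cannot tell metformin from a response that depends on sex. The small Foxo3 difference turned to -0.0188 after quantile normalization and -0.0112 after median centring, and ran from -0.0258 to 0.124 without single arrays. Replicate numbers gave no clear sign of pairing. Correlations of deviations between arrays with the same number ran from -0.176 to 0.235 (median -0.0118), 4 of 12 over 0.1. Between arrays with other numbers the median was 0.0198, with 8 of 36 over 0.1. In all, 5 of 12 arrays matched their own number best. Deviations of wild type arrays also hold their sex signal, so pairing is not excluded. With the number as a replicate block the counts were 1807, 3349 and 135.

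Outside the fits with sex signal, none of the 60 largest changes named turned direction. Under other settings 177, 174 and 159 values kept their side of the threshold and 3, 2 and 21 did not; without single arrays 216, 227 and 141 kept it and 24, 13 and 99 did not. In the fits with sex signal 31, 7 and 6 values kept their side of the threshold and 29, 27 and 54 lost it with the same sign. In comparison 2 another 6 values changed sign in these fits. How far dim probe sets lie above background could not be judged.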

Other observations

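The test of a retained transgene response was chosen after related results were seen. Genes of the circadian clock, which set daily rhythms in liver, differed between metformin-treated and untreated transgenic livers: 8 of 22 rose and 2 fell (9 and 2 when adjusted over the list alone), with a median of 0.29. The list itself was not called (camera, adjusted p = 0.133; adjusted p = 0.648 with an estimated correlation), but was without metformin-treated replicate 3 (adjusted p = 0.0417; adjusted p = 0.542 with an estimated correlation). In limma the clock output gene Ciart was higher by 2.82 ± 0.50 (adjusted p = 0.00265), the deubiquitinase Usp2 by 1.70 ± 0.33 (adjusted p = 0.00428), and the repressor Nfil3 fell by 1.01 ± 0.16 (adjusted p = 0.00126). None of these 3 passed with the sex covariate. The time of day at which livers were taken is not in the labels.

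Whether metformin-treated livers retain part of the transgene's response was not decided. Among the 650 genes called with the sex covariate in transgenic against wild type, 57.8% (376) had the same sign in metformin-treated against wild type livers within the arrays with Xist signal. This lies between the 50% and 60% set as bounds (51.1% with independent noise and no retained response), and genes that move together make the share less certain. The median change of the 650 genes there was 0.0507 of the transgene change within arrays with Y-linked signal (bootstrap over genes 0.0297 to 0.0704). Gpx3, picked after its values were seen, read 9.81 and 11.60 in metformin-treated replicates 2 and 3, and 6.91 and 6.89 in replicates 1 and 4. Differences from wild type within the arrays with Xist signal were 1.80 for Gpx3, 1.49 for Lepr, 0.66 for Igfbp1, 0.33 for Pdk4 and -0.12 for Afp.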
